A study of Homo sapiens with 18 samples.

How the data were processed

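The series measured the messenger RNA of FaDu and SCC154 cells (titled FADU-hfm and SCC154-hfm), made from 2 established human head and neck squamous carcinoma lines, with a 3′ tag kit (QuantSeq 3′ mRNA-seq), which reads the end of a transcript next to its poly(A) tail. Both lines carried a reporter that turns cells from red to green fluorescence for good after a period of low oxygen. Per the labels' protocols, the cells were grown as spheroids in plates that prevent attachment, dissociated with trypsin, sorted by fluorescence into red (non-hypoxic) and green (post-hypoxic) cells, and then cultured and passaged at ambient oxygen before RNA was extracted. The sorted fractions are thus populations compared after a shared period of normal culture, not during low oxygen.

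The authors deposited 1 table of whole-number read counts per gene symbol, with 41120 symbols and 18 libraries. The submitters' processing notes name FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, UMI-tools 1.1.5, featureCounts 1.5.1, DESeq2 and the hg38 build. The order and settings of these tools, the gene annotation, the strand setting and the handling of reads that match several genes are not given in the sources used here. Reads from a gene and an overlapping partner on the other strand therefore could not be told apart, and genes with close copies were treated as uncertain. A tag count depends on the poly(A) site and its annotated 3′ end, not on transcript length. Because UMI-tools is named but its role is not given, counting intervals and floors cover counting error only, whether or not duplicates were removed.

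Library totals ran from 1654719 to 2503573 counts, so that 1 CPM (a count scaled to the size of its library) stood for 1.68 to 2.44 counts. Of the 41120 symbols, 22591 had at least 1 count and 12291 passed edgeR's filterByExpr with the 4 groups. No symbol was blank and no column lacked a sample. Columns were matched to samples by their titles, and the group and replicate number of a library came from its title. Nothing in the labels says that the replicates of a group were separate cultures or sorts, so the p-values measure only the spread between these samples, which may be technical. Within groups, 32 pairs of replicates were compared by a chi-square test of their counts, for genes with a count of at least 10; the statistic per degree of freedom ran from 1.77 to 10.7, so that no pair matched within sampling noise and all 18 libraries were counted singly.

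Differences were tested on the deposited counts with edgeR 4.0.16 (R 4.3.3): trimmed-mean (TMM) factors, 1 quasi-likelihood model with 4 group means over all 18 libraries, and a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.148, with 14 residual degrees of freedom. The contrasts were post-hypoxic minus non-hypoxic in each line, the difference of these between the lines (the interaction), and non-hypoxic SCC154 minus non-hypoxic FaDu. HPV status and line are one and the same here. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Group means ± SD are CPM over TMM-scaled library sizes. A group with no count of a gene was given a floor of 3 counts over the group, and a ratio to a group with 1 or 2 counts its exact 95% counting interval.

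A set of 31 gene lists with 796 symbols was fixed, covering the response to low oxygen, metabolism, differentiation, mobility, immunity, proliferation, stress and other cell types. Of these symbols, 795 were in the table and 663 were tested. The 28 lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, adjusted over the lists of a contrast. Each was repeated with an estimated correlation and with fry. Of the lists for other cell types, those for fibroblasts and endothelial cells had 1 tested member each and the immune list had 0, so none could be tested as a list.

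The genes named by rule were, in each line, the 8 largest rises and the 8 largest falls with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the libraries of the 2 groups; up to 3 called members of each called list or each list with at least 4 called members; and 8 genes of the response to low oxygen (CA9, VEGFA, SLC2A1, NDRG1, ADM, BNIP3, PDK1 and LDHA) whatever their result. For the interaction the rule took up to 6 genes per direction, and between the lines the 6 largest differences per direction with a mean of at least 50 CPM, and CDKN2A. Other genes named were chosen after their values were seen, and are said to be. The values of some single genes are not reported here. The 9 tested Y-linked genes were left out of naming. The groups, the tests, the gene lists, the naming rule and the settings to be varied were all fixed before the data were examined; 2 further settings that leave out libraries were added later.

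Gene positions are those of GENCODE v29 on GRCh38, the same assembly as hg38, joined by symbol; 11587 of the tested genes had a position. The fits were tested on simulated data, with counts drawn from the means and spread of the real libraries. Each gene was drawn independently in each library, so that differences shared by genes or by libraries were not simulated. The shares and false calls hold for such data alone. In FaDu, over 12148 genes, 44.8% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 92.4% of those changed 4-fold were recovered, with 12 false calls among 153. In SCC154, over 12142 genes, the shares were 35.8%, 77.6% and 90.9%, with 9 false calls among 145. For the interaction with changes in SCC154 alone, the shares over 12142 genes were 7.46%, 43.3% and 81.8%.

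Replicate numbers are shared between the groups of a line. In FaDu the deviations of same-numbered libraries from their group means correlated over 12291 genes by 0.447, 0.178, 0.208 and 0.438 for replicates 1 to 4, each above 0.1, so that the numbers were taken to pair these libraries; the labels do not say what a number marks. Replicates 1 and 4 correlated best with their own number in both directions, replicate 2 in 1 direction and replicate 3 in neither. The blocked FaDu values are given beside the FaDu result. In SCC154 the correlations were 0.029, 0.292, 0.398 and 0.144 for replicates 2 to 5. Replicate 2 lay under 0.1, so that the SCC154 numbers were not taken to pair the libraries. Replicates 3, 4 and 5 still correlated best with their own number in both directions. Pairing the libraries of FaDu and not those of SCC154 thus rests on this bound. Alternatives were DESeq2's size factors (DESeq2 1.42.0), upper-quartile factors, DESeq2's own test, limma voom, no filter and a stricter filter (at least 5 CPM in at least 4 libraries), only the groups compared, replicate blocks, an added bound of 1 on the absolute log2 fold change, and each library left out in turn. Up to 100 splits of the libraries were drawn with a fixed seed. Between the groups of each line, 7 library measures were compared (total count, genes with a count, and the shares of mitochondrial mRNA, mitochondrial rRNA, ribosomal protein mRNA, MALAT1 with NEAT1, and the top 10 genes). In these 14 two-sided exact permutation tests, with 126 permutations each and without regard to pairs, the lowest p was 0.135, for mitochondrial mRNA in SCC154; the smallest p the design allows was 0.0079. Within the FaDu pairs the shares of mitochondrial mRNA, mitochondrial rRNA, MALAT1 with NEAT1 and the top 10 genes were lower in 4 of 4 post-hypoxic libraries, by means of 0.107, 0.0484, 0.0811 and 0.202 percentage points; 4 pairs allow no exact permutation p under 0.125.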

Results

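The data were counts of 3′ mRNA tags in 18 libraries of FaDu and SCC154 (titled FADU-hfm and SCC154-hfm), squamous carcinoma lines of the head and neck without (FaDu) and with (SCC154) human papillomavirus. Cells of both lines that had met low oxygen in spheroids were marked by a lasting switch from red to green fluorescence, sorted, and returned to normal culture. There were 4 non-hypoxic and 5 post-hypoxic FaDu libraries, and 5 non-hypoxic and 4 post-hypoxic SCC154 libraries. Library totals lay between 1654719 and 2503573 counts, and 12291 genes were tested. The comparison of sorted fractions within a line asked which transcripts still differed, after reoxygenation, in cells with a past of low oxygen.

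In post-hypoxic SCC154 cells, IRF9 rose most among the genes named by rule: its level went from 16.5 ± 4.89 CPM (SD, n = 5) to 58.6 ± 10.1 CPM (SD, n = 4), 3.56-fold. IRF9 encodes the DNA-binding part of the complex that carries the type I interferon signal to the nucleus. NANOS1, an RNA-binding repressor of translation, rose from 69.9 ± 17.0 to 138 ± 10.3 CPM, and MMP12, a secreted metalloprotease that degrades elastin, from 6.99 ± 2.71 to 19.6 ± 6.97 CPM. Among the genes named by rule the hair keratin KRT81 fell most, from 41.0 ± 8.11 to 6.75 ± 1.07 CPM, or 6.10-fold. CALD1, which encodes the actin-binding protein caldesmon, fell from 48.6 ± 5.79 to 12.2 ± 2.70 CPM, SLC7A2, a transporter of cationic amino acids, from 20.1 ± 5.27 to 5.12 ± 0.957 CPM, and NFIB, a transcription factor of the nuclear factor I family, from 60.01 ± 7.13 to 27.3 ± 7.21 CPM.

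By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 93 of the 12291 genes passed an adjusted p of 0.05 in SCC154, 41 higher and 52 lower, and 32 of them differed at least 2-fold. With upper-quartile factors 70 genes passed, 40 higher and 30 lower. The log2 fold change of IRF9 was 1.83 (SE 0.22, adjusted p = 9.75e-05 by edgeR), of KRT81 -2.61 (SE 0.24, adjusted p = 7.26e-07) and of CALD1 -1.98 (SE 0.14, adjusted p = 1.16e-08). NFIB followed with -1.14 (SE 0.16, adjusted p = 0.000431 by edgeR), SLC7A2 with -1.98 (SE 0.25, adjusted p = 0.000131) and LRATD1 with -2.05 (SE 0.26, adjusted p = 0.000131). NANOS1 had 0.98 (SE 0.16, adjusted p = 0.00312 by edgeR) and FHAD1 1.29 (SE 0.22, adjusted p = 0.00794). These 8 genes passed in each of the 29 other settings and leave-one-out fits. By position, IRF9 lies on chr14 (24161053 to 24166565), CALD1 on chr7 (134744252 to 134970728), NFIB on chr9 (14081843 to 14398983), SLC7A2 on chr8 (17497088 to 17570573), FHAD1 on chr1 (15247272 to 15400283) and KRT81 on chr12 (52285913 to 52291534). LRATD1 had no position under this symbol.

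The reads of 3 of the genes named by rule for their rise or fall in SCC154 could be shared with a neighbour. KRT81 lies inside the annotated span of KRT86 on the other strand and has close keratin relatives. The 3′ end of NANOS1 on chr10 (119029716 to 119033732) runs into the 3′ end of EIF3A, which averaged 1256 CPM. SRGAP3 overlaps THUMPD3 on the other strand and the antisense gene of THUMPD3 on its own strand, both at the end opposite to its 3′ end. Of the 3, NANOS1 alone meets its partner with both 3′ ends. The strand setting and the handling of reads that match several genes are not given in the sources used here. The levels of these 3 genes are therefore uncertain.

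The other 8 genes named by rule in SCC154 lay closer to the threshold. NMNAT2, an enzyme of NAD synthesis, had 1.04 (SE 0.25, adjusted p = 0.0453 by edgeR), MMP12 1.42 (SE 0.28, adjusted p = 0.0212), VWA1, an extracellular matrix protein, 1.00 (SE 0.22, adjusted p = 0.0346), RASGRF1, an activator of Ras, 0.90 (SE 0.19, adjusted p = 0.0321) and the cilium gene CFAP300 0.89 (SE 0.17, adjusted p = 0.0183). SRGAP3 had -1.16 (SE 0.26, adjusted p = 0.0368 by edgeR), CADPS2, which acts in the release of dense-core vesicles, -1.15 (SE 0.25, adjusted p = 0.0330) and the zinc-finger gene TSHZ2 -1.14 (SE 0.24, adjusted p = 0.0330). Each lost its call in some leave-one-out fits, with a highest edgeR adjusted p of 0.0589 for MMP12 (without non-hypoxic replicate 3; also lost without replicate 2, 0.0538), 0.0880 for CFAP300 and 0.160 for VWA1 (both without post-hypoxic replicate 4). Without post-hypoxic replicate 4, SRGAP3 had 0.160, CADPS2 0.140 and TSHZ2 0.149. RASGRF1 had 0.0866 without non-hypoxic replicate 5, and NMNAT2 0.144 without post-hypoxic replicate 2.

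The count of 93 rested on the number and choice of libraries. It was 20, 21 and 24 without non-hypoxic SCC154 replicate 2, 3 or 5, and 57 and 51 without replicate 1 or 4. Without post-hypoxic SCC154 replicate 2 or 4 it was 23 and 20, and without replicate 3 or 5 it was 163 and 190. Among the FaDu libraries, which share the estimate of spread, it was 59 without non-hypoxic replicate 3 and 55 without post-hypoxic replicate 3. A fit of the SCC154 libraries alone called 22 genes, DESeq2 203, and edgeR with no filter on low counts 291. With the replicate number as a block within each line it was 1052, and with a block shared across the lines 243. The SCC154 numbers were not taken to pair the libraries.

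**Figure D1:**
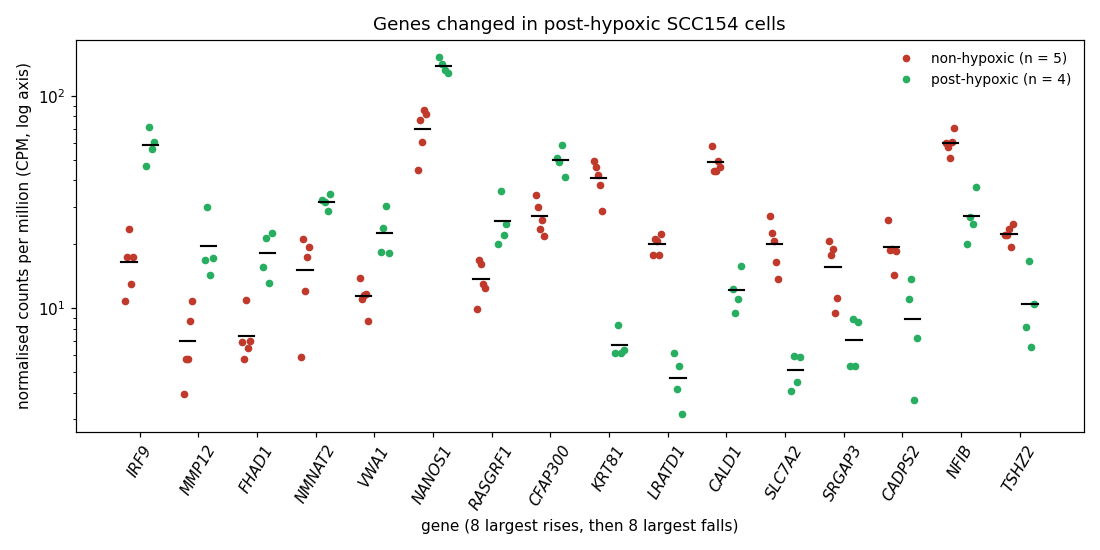
CPM (log axis) of the 16 genes named by rule in SCC154, with 1 point per library for the 5 non-hypoxic and 4 post-hypoxic libraries and the mean of each group. IRF9 goes from 16.5 to 58.6 CPM and KRT81 from 41.0 to 6.75 CPM. No overlap between the groups was a condition of the naming rule.

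None of the 8 fixed genes of the response to low oxygen passed the threshold in SCC154 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. BNIP3, a mitophagy receptor, had a log2 fold change of 0.46 (adjusted p = 0.152), LDHA 0.17 (0.611), ADM 0.25 (0.553), the glucose transporter SLC2A1 0.20 (0.677) and PDK1 0.01 (0.994). VEGFA had -0.48 (adjusted p = 0.353 by edgeR); 1 non-hypoxic library, replicate 1, had 32.1 CPM where the other 4 had 102 to 121 CPM, and without this library and post-hypoxic replicate 3 VEGFA passed (-0.81, adjusted p = 0.0311). NDRG1 had 0.76 (adjusted p = 0.587 by edgeR), with 71.6 CPM in post-hypoxic replicate 3 and 4.10 to 9.08 CPM in the other 3; without that library it had -1.03 (adjusted p = 0.284). CA9 had no count in the 5 non-hypoxic libraries and a mean of 0.606 CPM in the 4 post-hypoxic ones (adjusted p = 0.267 by edgeR), so that a difference was not detectable at this depth. CA9 also overlaps ARHGEF39 (28.8 CPM on average) on the other strand, at the end opposite to its 3′ end. With the replicate number as a block within each line, VEGFA (-0.70, adjusted p = 0.000348 by edgeR) and BNIP3 (0.37, 0.0468) passed and the others of the 8 did not. The SCC154 numbers were not taken to pair the libraries.

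As a group, 22 of the 26 tested HIF targets, genes switched on by the oxygen-sensing factors, were higher in post-hypoxic SCC154 cells, with a median log2 fold change of 0.24 and 0 members past the threshold, also when adjusted over the list alone. The members with the lowest p, chosen after their values were seen, were TMEM45A (0.77), BNIP3 (0.46) and FAM162A (0.35). The list was called higher by camera (adjusted p = 0.00591); with an estimated correlation it was not (adjusted p = 0.893). It was not called without post-hypoxic replicate 3 (adjusted p = 0.160 by camera) or without non-hypoxic replicate 1 (adjusted p = 0.0510).

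Genes of cell division and genome upkeep were called lower as lists in post-hypoxic SCC154 cells. Of 35 genes of DNA double-strand break repair 23 were lower (median -0.12, camera adjusted p = 0.0151), with 0 called over all genes and 6 lower when adjusted over the list alone. The latter were XRCC2 (-0.70), FANCD2 (-0.43), PRKDC (-0.67), which encodes the catalytic subunit of DNA-dependent protein kinase, BLM (-0.46), RBBP8 (-0.34) and BRIP1 (-0.27). Of 38 genes of G1/S and replication 27 were lower (median -0.10, camera adjusted p = 0.0458) and of 36 G2/M genes 25 (median -0.08, camera adjusted p = 0.0462), with 0 members of either called, also when adjusted over the list alone. With an estimated correlation these 3 calls were lost, with camera adjusted p of 0.827, 0.893 and 0.893.

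Of 16 tested histone genes 12 were lower (median -0.45, camera adjusted p = 0.0458; adjusted p = 0.827 with an estimated correlation). None passed over all genes; adjusted over the list alone, 6 were lower, among them H1-2 (-0.59), H1-4 (-1.17) and H4C3 (-0.60), and 2 were higher, among them H2BC21 (0.85). Most transcripts of replication-dependent histones have no poly(A) tail, so a 3′ tag library holds few of them.

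Leaving out 1 library ended some of these list calls in camera. Double-strand break repair lost its call without post-hypoxic SCC154 replicate 3 (adjusted p = 0.0915). The G1/S list lost it without SCC154 post-hypoxic replicate 3 (0.430), non-hypoxic replicates 1 (0.107), 4 (0.0728) and 5 (0.0768), and FaDu non-hypoxic replicates 1 (0.0565) and 3 (0.0518) and post-hypoxic replicate 4 (0.0537). The G2/M list lost it in 13 of 18 such fits, with adjusted p of 0.299 without SCC154 post-hypoxic replicate 3, 0.256, 0.198 and 0.0768 without non-hypoxic replicates 2, 4 and 5, and 0.0509 to 0.0712 without each of the 9 FaDu libraries. The histone list lost it without SCC154 post-hypoxic replicate 2 (0.0810) and non-hypoxic replicate 4 (0.0728), and without FaDu non-hypoxic replicates 1 (0.0590) and 3 (0.0518) and post-hypoxic replicate 1 (0.0508). The number of called lists, 5 with all libraries, was 9 without SCC154 post-hypoxic replicate 5, 3 without SCC154 non-hypoxic replicate 1 or 5 or FaDu post-hypoxic replicate 1 or 4, and 2 without FaDu non-hypoxic replicate 1 or 3.

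Among proteases of the extracellular matrix and their inhibitors, 3 of 20 tested genes rose in SCC154: MMP12, TIMP1, an inhibitor of metalloproteases (27.4 ± 2.87 to 41.7 ± 6.50 CPM), and the lysosomal protease CTSL (140 ± 23.6 to 212 ± 41.3 CPM). Adjusted over the list alone 6 were higher and 2 lower, and the list itself was not called (camera adjusted p = 0.0704). Of 16 basal keratinocyte genes 2 were called lower: SOX2, a transcription factor of squamous progenitors (26.99 ± 8.20 to 12.6 ± 1.099 CPM), and DST, a linker of the cytoskeleton to hemidesmosomes (769 ± 40.7 to 517 ± 109 CPM). By sign 10 of the 16 were higher and 6 lower (median 0.07), and the list itself was not called (camera adjusted p = 0.984). Both lists lie outside the naming rule, so these genes apart from MMP12 were chosen after their values were seen. Of 32 interferon-stimulated genes IRF9 alone passed over all genes (2 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.498).

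In FaDu, 0 of the 12291 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (lowest adjusted p = 0.145). There were 298 genes with an unadjusted p under 0.05, where 614.55 would be expected by chance; limma voom called 0 genes and DESeq2 3. With a block shared across the lines 0 genes passed, and 0 with the paired libraries and no block. With the replicate number as a block within each line, as the FaDu libraries were taken to be paired, 7 genes passed. Thymidine kinase TK1, an enzyme of DNA precursor supply, rose from 127 ± 14.6 CPM (SD, n = 4) to 220 ± 57.6 CPM (SD, n = 5), and PM20D2, a peptidase, from 72.2 ± 7.48 to 109 ± 14.8 CPM. The long non-coding RNA LINC02582 rose from 13.99 ± 5.11 to 34.8 ± 10.8 CPM, and the RNA-binding protein gene IGF2BP1 from 19.7 ± 5.44 to 35.3 ± 3.33 CPM. INHBA, which encodes the activin A subunit, fell from 15.7 ± 6.02 to 7.86 ± 2.92 CPM.

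In that blocked edgeR fit, with Benjamini-Hochberg adjustment, the log2 fold changes were 0.65 for TK1 (adjusted p = 0.00678), 0.63 for PM20D2 (0.00678), 1.11 for LINC02582 (0.0102), 0.88 for IGF2BP1 (0.0266) and -1.11 for INHBA (0.0300), each in the same direction in 4 of 4 pairs. The remaining 2 calls are uncertain. PTMAP2 (-1.34, adjusted p = 0.0300 by edgeR) is a pseudogene whose reads could come from its parent gene, and MT-TS1 (-6.13, adjusted p = 0.00678) had counts in 1 library, non-hypoxic replicate 3. These 7 genes lie outside the naming rule and were chosen after their values were seen. Without the block, TK1 passed when post-hypoxic replicate 1 was left out (1 gene, adjusted p = 0.00726), and TK1, PM20D2 and LINC02582 passed with DESeq2. With no filter on low counts, edgeR called 10 genes.

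The 8 fixed genes of the response to low oxygen each had an edgeR adjusted p of 1 in FaDu. Their log2 fold changes were 0.17 for CA9, 0.28 for VEGFA, -0.02 for SLC2A1, -0.19 for NDRG1, -0.36 for ADM, -0.28 for BNIP3, -0.07 for PDK1 and -0.19 for LDHA. Of the 26 HIF targets 16 were lower (camera adjusted p = 0.173); with the replicate block the list was called lower (adjusted p = 0.0341). Its camera adjusted p was 0.819 with an estimated correlation and no block, and its score in post-hypoxic replicate 1 was -0.68, against -0.05 to 0.20 in the other 4.

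As lists, 4 groups were called higher and 2 lower in post-hypoxic FaDu cells, with shifts well below 2-fold and 0 members called, also when adjusted over each list alone. Of 15 genes of MHC class I antigen presentation 13 were higher, with a median of 0.11 (HLA-E 0.29, TAP1 0.32), and of 20 matrix proteases and inhibitors 16, with a median of 0.12 (MMP14 0.30). Stem-cell markers were higher in 7 of 11 (median 0.22; BMI1 0.65), and interferon-stimulated genes in 19 of 32 (median 0.06; ISG15 0.33). All 13 mitochondrially encoded transcripts were lower (median -0.13; MT-CYB -0.27), and so were 59 of 74 ribosomal protein genes (median -0.06; RPL14 -0.25). The camera adjusted p was 0.0233 for MHC class I, proteases, mitochondrial transcripts and ribosomal proteins, and 0.0254 for stem-cell markers and interferon-stimulated genes. With an estimated correlation none was called, with adjusted p of 0.603, 0.375, 0.747, 0.819, 0.307 and 0.747 in this order. With the replicate block, stem-cell markers (adjusted p = 0.0600) and ribosomal proteins (adjusted p = 0.0944) were not called by camera, while genes of the unfolded protein response (adjusted p = 0.0132) and histones (adjusted p = 0.0376) were called higher. The share of all counts held by the 13 mitochondrially encoded transcripts was lower in 4 of 4 pairs, and so were those of mitochondrial rRNA, of MALAT1 with NEAT1 and of the top 10 genes, so that the fall of the mitochondrial list went along with other differences between libraries. The unfolded protein response and histone lists had camera adjusted p of 0.819 and 0.747 with an estimated correlation and no block. The members named here were chosen after their values were seen.

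Single FaDu libraries ended these list calls as well, by camera. MHC class I was lost without non-hypoxic replicate 3 (adjusted p = 0.0556) and post-hypoxic replicates 1 (0.0614), 2 (0.0559) and 4 (0.0791). Proteases were lost without non-hypoxic replicate 3 (0.0556) and post-hypoxic replicate 4 (0.246). Stem-cell markers were lost without non-hypoxic replicates 2 (0.0508), 3 (0.0875) and 4 (0.0806) and post-hypoxic replicates 1 (0.109), 2 (0.0567) and 4 (0.0953). Interferon-stimulated genes were lost without non-hypoxic replicates 3 (0.399) and 4 (0.488) and post-hypoxic replicates 1 (0.351) and 2 (0.290). Mitochondrial transcripts were lost without non-hypoxic replicates 1 (0.289) and 2 (0.335) and post-hypoxic replicates 2 (0.0559), 3 (0.136) and 4 (0.246). Ribosomal proteins were lost without non-hypoxic replicates 3 (0.337) and 4 (0.882) and post-hypoxic replicates 1 (0.302), 2 (0.0559) and 5 (0.13). The number of called lists was 1 without non-hypoxic replicate 3 or post-hypoxic replicate 2, and 2 without post-hypoxic replicate 4.

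**Figure D2:**
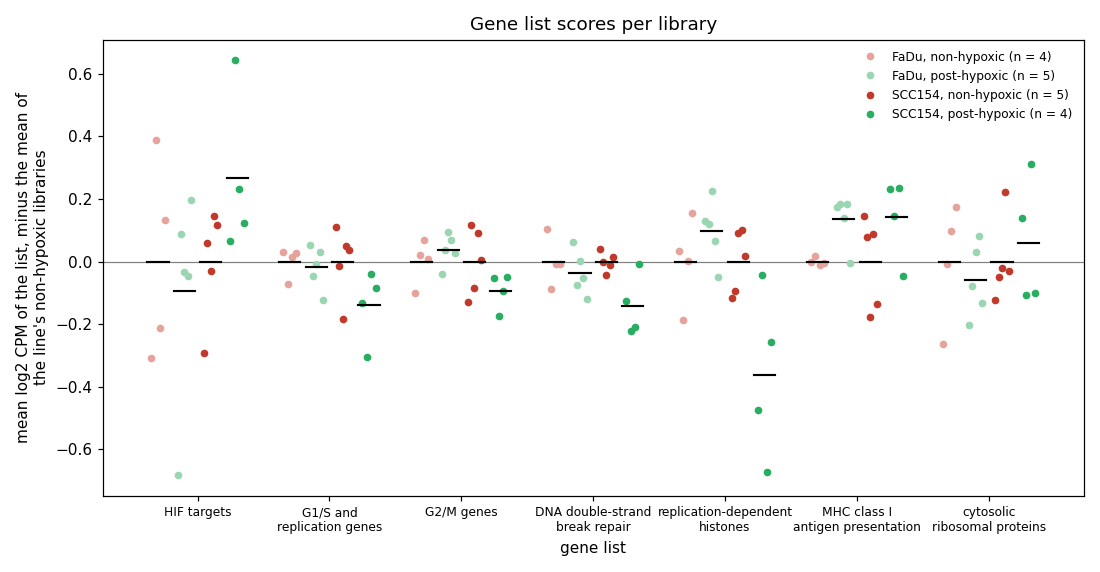
Score of 7 gene lists in each of the 18 libraries (mean log2 CPM of its tested genes minus the mean of the line's non-hypoxic libraries), with 1 point per library and groups side by side. In SCC154, 22 of 26 HIF targets were higher and 12 of 16 histone genes lower in the post-hypoxic group, and single libraries lie apart from their group.

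The change in SCC154 was compared with that in FaDu by the interaction. CALD1 fell in SCC154 while it had 194 ± 14.01 and 202 ± 9.55 CPM in non-hypoxic and post-hypoxic FaDu cells (log2 difference of the changes -2.03, SE 0.18, adjusted p = 5.48e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). NFIB fell in SCC154 and had 49.3 ± 3.64 and 58.7 ± 8.19 CPM in FaDu (-1.40, SE 0.22, adjusted p = 0.00811 by edgeR). These 2 genes were the ones that passed out of 12291, and both did in the 28 other settings and leave-one-out fits. IRF9 had a log2 fold change of 0.35 in FaDu, and its difference between the lines did not pass (1.48, adjusted p = 0.196 by edgeR). DESeq2 called 19 genes for the interaction and edgeR with no filter on low counts 51. With the replicate number as a block within each line edgeR called 224, and with a block shared across the lines 5. The SCC154 numbers were not taken to pair the libraries.

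Of the lists, HIF targets (22 of 26 higher, median difference 0.28, camera adjusted p = 0.00247) and ribosomal proteins (56 of 74 higher, 0.16, adjusted p = 0.0123) changed more in the higher direction in SCC154 than in FaDu. Histones (14 of 16 lower, -0.48, camera adjusted p = 0.0123) and G2/M genes (28 of 36 lower, -0.13, adjusted p = 0.0347) changed more in the lower direction. No member was called, and 0 were when adjusted over each list alone. With an estimated correlation each of the 4 had an adjusted p of 0.930. HIF targets were not called without FaDu post-hypoxic replicate 1 (0.0591) or SCC154 post-hypoxic replicate 3 (0.0618). Ribosomal proteins were not called without FaDu non-hypoxic replicates 3 (0.0840) and 4 (0.179), FaDu post-hypoxic replicate 1 (0.0605) or SCC154 post-hypoxic replicate 4 (0.273). G2/M genes were not called without FaDu non-hypoxic replicates 1 (0.166) and 4 (0.0758), FaDu post-hypoxic replicates 3 (0.0949) and 4 (0.0755), SCC154 non-hypoxic replicates 2 (0.177), 4 (0.132) and 5 (0.0519) or SCC154 post-hypoxic replicate 3 (0.152).

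No gene passed in the same direction in both lines. At an unadjusted p under 0.05, 5 genes were higher in both lines, where 11.1 would be shared by independent lists (Fisher's exact test, p = 0.0586), and 10 were lower in both, where 12.2 would be (p = 0.650). Of the 93 genes called in SCC154, 42 had a change of the same sign in FaDu. With the replicate block in each line, INHBA passed in both, with -1.11 in FaDu and -0.40 in SCC154 (adjusted p = 0.0300 and 0.00261 by edgeR).

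**Figure D3:**
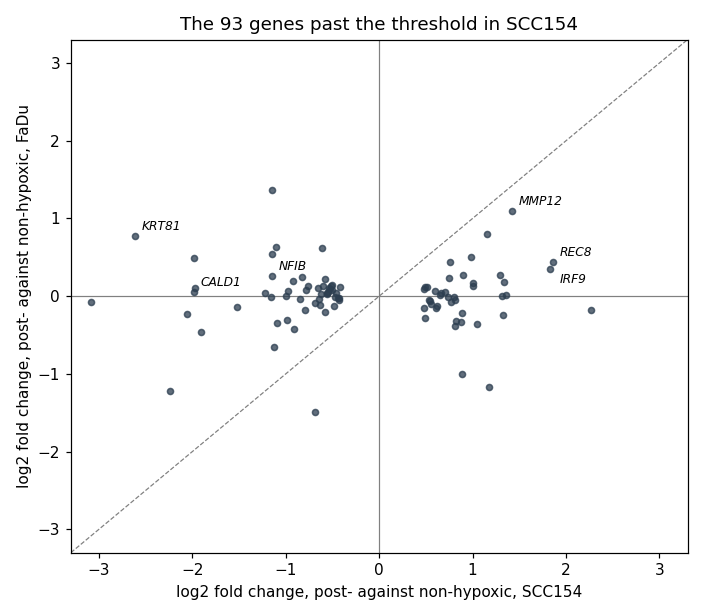
Log2 fold change (post-hypoxic over non-hypoxic) in FaDu against that in SCC154 for the 93 genes called in SCC154, with 1 point per gene. Of the 93, 42 have the same sign in FaDu, and CALD1 and NFIB are the 2 whose change differed between the lines by the interaction test.

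The non-hypoxic populations served as the background for the difference between the lines. SCC154 expressed SEMA5A, a semaphorin of the axon guidance family, at 188 ± 7.59 CPM (SD, n = 5) where FaDu (n = 4) had no count, at least 518-fold higher against a floor of 3 counts over the group. TNFRSF10D, a decoy receptor for the death ligand TRAIL (143 ± 45.5 CPM, at least 395-fold), TMX3 (140 ± 11.8 CPM, at least 386-fold), ANKRD1, a target of YAP (115 ± 24.4 CPM, at least 316-fold), AJUBA, a LIM protein of cell junctions (114 ± 17.8 CPM, at least 314-fold), and SNRPN (113 ± 11.4 CPM, at least 310-fold) were also without a count in FaDu. FaDu expressed PRKAA2, a catalytic subunit of the energy sensor AMPK (141 ± 13.8 CPM, at least 497-fold), and the cancer-testis antigen MAGEA4 (115 ± 16.6 CPM, at least 403-fold), both without a count in SCC154.

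Few counts in SCC154 were found for 4 further genes higher in FaDu. The ratio was 3425 (95% counting interval 615 to 135294) for EEF1A2, a translation elongation factor at 325 ± 20.3 CPM, 1228 (340 to 10140) for the actin-bundling LCP1 at 233 ± 20.3 CPM, 1350 (242 to 53305) for TMEM161B at 128 ± 31.6 CPM and 1108 (199 to 43782) for ARHGAP6 at 105 ± 11.1 CPM. CDKN2A, whose protein p16 is a marker of HPV-positive tumours, was 2.85-fold higher in SCC154, with 193 ± 6.03 against 67.8 ± 0.984 CPM (log2 fold change 1.51, SE 0.10, adjusted p = 3.58e-12 by edgeR). SNRPN overlaps SNHG14 and MAGEA4 has close relatives in its family, so their reads could be shared.

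Between the non-hypoxic lines 8472 of the 12291 genes passed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4235 higher and 4237 lower in SCC154, and 4606 of them differed at least 2-fold. Of 20 matrix proteases and inhibitors 17 were called higher in SCC154 and 0 lower, among them TIMP2 (5.27) and PLAUR (3.67), chosen after their values were seen like the other list members named here. This list was called by camera (adjusted p = 2.54e-06; adjusted p = 0.0179 with an estimated correlation). TGF-beta targets (16 of 22 called higher, 3 lower; TGFBI 4.13) and HPV-associated host genes (7 of 13 higher, 2 lower; TAF7L 5.48) had camera adjusted p of 0.000127 and 0.0118, and an adjusted p of 0.0866 each with an estimated correlation. Ribosomal proteins (54 of 74 called lower, 5 higher) and nuclear-encoded subunits of oxidative phosphorylation (37 of 53 called lower, 1 higher; NDUFS8 -1.73) had camera adjusted p of 7.26e-05 and 0.000139, lost with an estimated correlation (adjusted p = 0.673 and 0.740). Fry's test of a shared direction kept both (adjusted p = 0.000150 and 0.000887) and called 22 lists between the lines. It does not weigh members against other genes, most of which differed here. In MHC class I antigen presentation 10 of 15 were called lower and 3 higher (camera adjusted p = 0.0406; adjusted p = 0.490 with an estimated correlation), with HLA-C at -5.95; short reads of this polymorphic gene can fail to match the reference allele.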

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

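Of the tests below, the one of the HIF target list without post-hypoxic replicate 3 and the 3 of IRF9 and REC8 were chosen only after the result was seen, as was the setting that leaves out 2 SCC154 libraries together.

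IRF9 and REC8, 2 genes 5288 bases apart on chr14, rose together in post-hypoxic SCC154 cells, by 1.83 and 1.86 on the log2 scale. REC8, a cohesin subunit of meiosis, went from 2.84 to 10.7 CPM (adjusted p = 0.00169 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), below the level of the naming rule; it was chosen after its values were seen, and its level is uncertain, as its 3′ end overlaps IPO4 on the other strand. The tables argue against a general interferon response, as the other 31 tested interferon-stimulated genes had a median of 0.0782 (interquartile range 0.42), far below the IRF9 change. The 10 tested genes on each side had a median of 0.18 (interquartile range 0.37), where 3 copies against 2 in all cells would give 0.58. This argues against such a gain of the whole region. A gain of the 2 genes alone, in part of the cells or on more than 2 starting copies was not tested. Of the 20 flanking genes 14 were higher, and on chr14 as a whole 75.2% of 363 genes were. The tables also argue against a single library, since the lowest fold of the 2 genes over 9 fits without 1 SCC154 library was 3.24. What stays open beside this is a local difference of the 2 genes between the sorted populations, which may be a trace of low oxygen or of the clones that were sorted. Neither was tested, and the difference from FaDu did not pass for either gene (adjusted p = 0.196 and 0.381 by edgeR).

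The HIF target list was called higher in post-hypoxic SCC154 cells by camera, but not with an estimated correlation (adjusted p = 0.893). Without post-hypoxic replicate 3, which had the outlying NDRG1 level, its camera adjusted p was 0.160, and without this library and non-hypoxic replicate 1 it was 0.440, so the call rests on single libraries. In 19 of 100 permutations of the SCC154 libraries between the groups, the real grouping included, the list reached a camera p as low as in the real one (2.11e-04; lowest of the others 8.25e-08), consistent with members that move together between libraries whatever the group. A lasting response to low oxygen is not excluded by these values, but they do not set it apart from that variation.

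The change differed between the lines for CALD1 (log2 difference -2.03) and NFIB (-1.40) by the interaction test, and for the lists of HIF targets (median difference 0.28), ribosomal proteins (0.16), histones (-0.48) and G2/M genes (-0.13) by camera. Each of the 4 lists had a camera adjusted p of 0.930 with an estimated correlation, fry's test of a shared direction called 0 lists, and 60 of 100 splits gave as many lists.

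In further values 1 library lay far from the rest of its group, measured by its gap to the nearest library over the range of the group. This was so for 18 of 166 groups of values tested, where 1 in 20 would be 8.3. That rate holds for independent, normally spread values. These groups share libraries and genes were named from the same data. A group with counts in 1 library alone has a ratio of 1 whatever the count. The excess over 8.3 is therefore not a test. In post-hypoxic SCC154, NDRG1 was at 71.6 CPM in replicate 3 against 4.10 to 9.08 (ratio 0.926), KRT81 at 8.35 CPM in replicate 3 against 6.14 to 6.35 (0.905), and LDHA at 482 CPM in replicate 4 against 304 to 326 (0.877). In non-hypoxic SCC154, replicate 1 was low for VEGFA, with 32.1 CPM against 102 to 121 (ratio 0.784), and for TNFRSF10D, with 64.7 CPM against 151 to 175 (0.782). Replicate 3 was high for FHAD1, with 10.9 CPM against 5.80 to 7.05 (0.756), and replicate 4 for SNRPN, with 133 CPM against 106 to 111 (0.813), and for the share of ribosomal protein mRNA, with 5.23% against 4.35% to 4.58% (0.747). Counts in 1 non-hypoxic SCC154 library gave a ratio of 1 for ARHGAP6 (replicate 5, 0.415 CPM), EEF1A2 (replicate 1, 0.494 CPM) and TMEM161B (replicate 3, 0.575 CPM), where the other 4 had none.

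In post-hypoxic FaDu, CALD1 was at 185 CPM in replicate 1 against 202 to 209 (ratio 0.711), PTMAP2 at 45.8 CPM in replicate 1 against 11.04 to 14.5 (0.900), and LINC02582 at 53.7 CPM in replicate 5 against 26.3 to 33.2 (0.747). In non-hypoxic FaDu, MT-TS1 was at 15.97 CPM in replicate 3 and at 0 in the other 3 (ratio 1). Among list scores of post-hypoxic FaDu, HIF targets lay at -0.68 in replicate 1 against -0.05 to 0.20 (ratio 0.724), MHC class I genes at -0.01 in replicate 5 against 0.14 to 0.18 (0.768), and matrix proteases at 0.35 in replicate 4 against 0.06 to 0.13 (0.783).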

How the results depend on the processing

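The settings "paired libraries only" and "both libraries that stand apart left out" were chosen after seeing the data.

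Each called gene named by rule kept its direction in each setting run. Of the 16 genes named in SCC154, 7 lost their call with only the groups compared, 6 with the paired libraries and 5 without the libraries that stand apart, and 0 did with the other factors, tests, filters and blocks; 2 to 8 did without 1 SCC154 library and 0 to 2 without 1 FaDu library. Among genes not called, NDRG1, PDK1 and LDHA in SCC154 and NDRG1, PDK1 and SLC2A1 in FaDu changed sign in some settings. The number of genes called in SCC154 (93) was 32 with a log2 bound of 1, 203 with DESeq2, 291 with no filter on low counts, 22 with only the groups compared and 51 with the libraries that have a same-numbered partner; without 1 library it ran from 20 to 190. It stayed within 1.5 times of 93 with DESeq2's size factors (92), upper-quartile factors (70), voom (131), a stricter filter (94) and without the libraries that stand apart, non-hypoxic replicate 1 and post-hypoxic replicate 3 (72). In FaDu (0 genes) DESeq2 gave 3, no filter 10, the block 7, and leaving out 1 library 0 to 1. The interaction (2 genes) had 19 with DESeq2 and 51 with no filter. The lines (8472 genes) had 4606 with the log2 bound. Without the low-count filter, more genes with few counts enter the fit; the cause of the other shifts was not tested.

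With the replicate number as a block, SCC154 had 1052 genes, among them all 93, the interaction 224, among them both, and the genes changed in both lines 1. With numbers as 1 block shared across the lines, SCC154 had 243, the interaction 5 and FaDu 0, so that 0 of its 7 genes passed; with the paired libraries and no block FaDu had 0 as well. In SCC154 the deviations of same-numbered libraries correlated by 0.029, 0.292, 0.398 and 0.144 for replicates 2 to 5. Replicates 3, 4 and 5 correlated best with their own number and replicate 2 did not, so that the block rests on a hint from the data. Apart from the FaDu genes and lists given beside their results, the block ended the calls of G1/S genes in SCC154 (adjusted p = 0.112) and ribosomal proteins in the interaction (0.0544) and of no other called gene or list. It added glycolysis, oxidative phosphorylation and MHC class I genes, all higher, in SCC154, and glycolysis and mitochondrially encoded transcripts, higher, and the unfolded protein response, lower, in the interaction. These lists had camera adjusted p of 0.893 each in SCC154 and 0.930 each in the interaction with an estimated correlation and no block. Of the 8 fixed genes of the response to low oxygen, the block called VEGFA (-0.70, adjusted p = 0.000348 by edgeR) and BNIP3 (0.37, 0.0468) in SCC154. Same-numbered libraries of different lines correlated by 0.075 on average.

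Called lists numbered 0 with an estimated correlation and 0 with fry's test of a shared direction in FaDu, SCC154 and the interaction. Fry's mixed test asks whether members changed in either direction, not whether they moved together. For matrix proteases it gave an adjusted p of 2.62e-06 in SCC154, 0.0208 in the interaction and 0.928 in FaDu. Other lists passed this test in SCC154 too, among them double-strand break repair (adjusted p = 0.000368), basal keratinocyte genes (0.000358) and histones (0.00272). Basal keratinocyte genes also had 0.0208 in the interaction. Lists called by camera in SCC154 numbered 3 with the paired libraries and 2 without the libraries that stand apart. Without 1 library there were 1 to 8 in FaDu, 2 to 9 in SCC154 and 3 to 6 in the interaction.

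The interaction could not be run with only the groups compared, nor the lines with a block within each line. List tests were not run with only the groups compared, under the gene filters or with other gene tests. At about 2 counts per CPM, genes under 10 CPM carry a large counting error.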

Other observations

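The tests of splits and of neighbouring genes in this part were chosen before their own results were seen. The correlation of neighbours and the medians of chromosomes and of large windows had been looked at by then, and they foretold in part the test of genes 50 places apart. The splits for genes 50 places apart were added after the other tests of neighbours had been seen.

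Further genes called in post-hypoxic SCC154 cells were chosen here after their values were seen. Myosin light chain kinase MYLK rose from 147 ± 8.01 to 250 ± 24.4 CPM, the giant scaffold protein AHNAK from 301 ± 31.5 to 420 ± 75.7 CPM and the membrane protease ST14 from 108 ± 10.4 to 151 ± 2.90 CPM. The follistatin gene FST fell from 121 ± 13.5 to 66.9 ± 16.6 CPM, INHBB, a subunit of its ligand activin B, from 86.3 ± 11.6 to 53.7 ± 8.004 CPM, and NAMPT, the rate-limiting enzyme of the NAD salvage pathway, from 602 ± 31.6 to 416 ± 34.6 CPM. VHL, part of the ubiquitin ligase that marks HIF proteins for degradation, fell from 87.4 ± 8.10 to 61.2 ± 8.25 CPM (log2 fold change -0.52, adjusted p = 0.0416 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

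Between the non-hypoxic lines, 5 further lists were called by camera. NF-kB targets and cytokines were higher in SCC154 (18 of 23 called higher, 1 lower; adjusted p = 0.00135), as were partial EMT genes (15 of 22 higher, 5 lower; adjusted p = 0.0436) and p53 targets (14 of 23 higher, 4 lower; adjusted p = 0.0428). Glycolysis enzymes (11 of 18 lower, 2 higher; ENO1 -1.35, LDHB -1.58) and cholesterol synthesis (13 of 23 lower, 3 higher) were lower, each with a camera adjusted p of 0.0445. With an estimated correlation the adjusted p of the 5 lists was 0.193, 0.334, 0.334, 0.673 and 0.762.

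Other splits of the libraries into groups of the same sizes were tested in the same way. In SCC154, 2 of 100 splits, the real one included, gave as many genes as the real one (93 genes, highest of the others 285, the next 6). Few groupings thus reach 93 genes, but 1 that cuts across the sorted groups exceeds it, so that chance is not excluded. Each split regrouped both lines at once, and the split with 285 genes also gave 241 in FaDu and 65 in both lines. The split with 285 genes set post-hypoxic replicates 2 and 4 with non-hypoxic replicates 4 and 5 against the rest, which points to a structure of the samples beside the sorted groups. For the interaction 3 of 100 splits, the real one included, gave as many (2 genes, highest 485). The other 2, with 485 and 259 genes, parted 0 FaDu pairs. The 14 splits that part all 4 FaDu pairs like the real one are too few for a share under 0.05, so that chance is not excluded. Between the lines 1 of 100 splits, the real one, gave 8472 genes (highest of the others 6700). Each other split mixes the 2 lines within a group, so that these splits do not test chance. In FaDu (highest 529) and for genes changed in both lines (highest 65) the real count was 0, which 100 of 100 splits reach by definition, so that these splits do not test chance. With the pairs as a block, 1 of the 8 FaDu splits, the real one, gave 7 genes (highest of the others 4); these splits are too few for a share under 0.05. For the number of called lists, 46 of 100 splits in FaDu (6 lists, highest 13), 46 of 100 in SCC154 (5 lists, highest 9) and 60 of 100 for the interaction (4 lists, highest 10) gave as many, and chance cannot be excluded. Of the 14 FaDu splits that part all 4 pairs, 2 gave at least 6 lists, the real one included (highest of the others 7); these are too few for a share under 0.05.

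The highest FaDu split, with 529 genes, set replicates 1 and 2 of both groups and post-hypoxic replicate 5 against replicates 3 and 4, and each of the 4 splits with over 100 genes kept replicates 3 and 4 of both groups together. Of the 100 splits, 14 parted all 4 pairs like the real one and gave at most 0 genes, while the 86 that parted fewer gave up to 529. The 5 that parted 0 pairs gave 529, 104, 1, 0 and 0 genes, so that the large counts went with replicates 3 and 4 and not with all numbers alike.

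In post-hypoxic SCC154 cells, genes next to each other on a chromosome tended to change together: over 10402 genes with at least 5 CPM, the log2 fold changes of neighbours correlated by 0.104, where the highest of 1000 shuffled gene orders gave 0.0350 (genes are not independent replicates); in FaDu they correlated by 0.0484 (highest shuffled 0.0312), and 107 of the 125 other splits of the SCC154 libraries lay above 0.0350 too. On chr14, 75.2% of 363 genes were higher (median 0.15), while the median was -0.14 on chr21 and -0.11 on chr4. The tables argue against a bias of GC content or transcript length, as the correlation was 0.0959 after their trend was removed (highest shuffled 0.0311). Of 126 splits of the SCC154 libraries, 3, the real one included, reached the real value (0.104, highest of the others 0.117). Few groupings thus reach it, but others that cut across the sorted groups exceed it. Library differences that do not follow these groups are therefore not excluded. Genes 50 places apart correlated by 0.0505 in SCC154 (highest shuffled 0.0315) and by -0.0131 in FaDu, and 2 of 126 splits, the real one included, reached the real value (0.0520, highest of the others 0.0584), consistent with a hypothesis that the sorted SCC154 populations differ in the dosage of chromosome arms in part of their cells. A difference of chromatin state over large domains stays open too, as DNA was not measured. So do library differences over such distances, as a split across the sorted groups gave the higher value.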
